A study of Sus scrofa with 4 samples.

How the data were processed

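Umbilical cord blood of Yorkshire piglets was taken at birth from vein and artery into EDTA, and exosomes were pelleted from the plasma by filtration and ultracentrifugation, per the labels' protocols. Small RNA libraries were made with a TruSeq small RNA kit from pools of 3 normal or 3 IUGR piglets and sequenced as single reads of 36 bases, per the labels' protocols. The genome build Sscrofa 10.2 is named in the submitters' processing notes, and the aligner, the counting and the normalization method are not given in the sources used here.

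The authors deposited 4 tables, each comparing 2 libraries and listing miRNA rows with a name, a sequence, raw reads, normalized reads, a fold change and p-values. The raw columns hold estimated counts, per the file headers and the values deposited: reads shared between rows are split into fractions. The normalized columns hold a signal that equals the deposited raw reads times a single factor per library, 1.90 for normal vein, 4.70 for IUGR vein, 5.89 for normal artery and 3.18 for IUGR artery. How the authors set these factors is not given in the sources used here. The authors' fold column is the ratio of the normalized values, per the file headers. The authors' p-value column is displaced against its rows, since its heading stands inside the column, so no deposited p-value was taken for its row. Fisher's exact test was recomputed on the rounded normalized values and column totals. Of its p-values, 409 of 409 (IUGR vessels), 481 of 482 (artery), 498 of 517 (vein) and 581 of 581 (normal vessels) lay within 1% of some value anywhere in the deposited column. In their own row 56, 43, 40 and 27 did, in the same order. With an absolute log2 fold of at least 1 and a p of at most 0.05, the recomputed test gave every row that the authors' deposited tables mark as different.

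The sample labels give the vessel and a number. Whether a library is normal or IUGR was read from the letters N and I of the column names, and the vessel of each column from the tables' names, in which J stands only in the vein table and D only in the artery table. The 4 tables were joined by name and sequence into 664 rows, 268 of them present in all 4. A row absent from a table was taken as 0 in both of its libraries, which the column totals bear out. Genome positions were not used here. Rows that share a sequence (75 rows, such as miR-192 and miR-215, miR-194a and miR-194b, or miR-17-5p and miR-106a) hold equal parts of the same reads and cannot be told apart. Where several rows share a mature name, the most abundant stands for it in lists and named miRNAs.

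Each 2-library comparison used log2 of the normalized value plus 1 over rows with a summed value of at least 50, and counted rows at least 2-fold apart. Rows that match kit oligonucleotides, described below, were part of these counts unless a setting left them out. Folds in the text are ratios of values plus 1. With 1 library per condition no test across samples was made. The 95% interval of a ratio is an exact conditional binomial (Clopper-Pearson) interval on rounded reads and covers counting error only, as do the exact binomial intervals of shares. In simulated reads for IUGR versus normal in vein it held the true log2 ratio of 0 in 96.8% and of 1 in 96.1% of draws over 123 rows. Where a library had no read, the fold is a bound against 3 counts, which are worth 5.71, 14.1, 17.7 and 9.54 normalized reads in normal vein, IUGR vein, normal artery and IUGR artery. Depth differed 2.96-fold between the vein and artery libraries of normal piglets, and 148, 82, 94 and 104 rows had at least 10 reads, in the same order.

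Before the data were examined, 15 miRNA lists were fixed by miRNA number: erythroid, platelet and myeloid, lymphoid and inflammatory, endothelial and angiogenic, muscle, liver, epithelial, neural, imprinted DLK1-DIO3, the X-linked cluster of miR-424, miR-503, miR-450 and miR-542, hypoxia, let-7, 17-92, miR-30 and miR-29. A list's median log2 ratio was placed among 10000 random lists of the same size drawn within 5 bins of mean abundance, over 60 pairs of list and comparison, as a description of these libraries. The rule for named miRNAs, fixed at the same time, took per comparison the 10 highest and 10 lowest named miRNAs, the 5 most abundant of each library and list members at least 2-fold apart. Rows outside it (the oligonucleotide matches, the predicted candidate called by DESeq2, and members printed as unchanged) were chosen after their values were seen.

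Agreement between changes was tested by Pearson and Spearman correlation across rows with 100000 permutations, two-sided. Vein and artery were compared over all 4 libraries with edgeR 4.0.16 (quasi-likelihood test, TMM, limma 3.58.1, R 4.3.3) on raw counts rounded to whole numbers, for rows whose summed normalized value was at least 100, at a Benjamini-Hochberg adjusted p of 0.05. The pool was left out of this fit and added as a block in an alternative, since column letters pair each vein library with the artery library of the same condition. Pool and condition coincide, so the correlation of the IUGR change between vessels, 0.71, does not check that pairing. In data simulated for this contrast with 130 rows tested, edgeR recovered 90.0% of 40 rows changed 4-fold at a dispersion set to 0.1, with 2 unchanged rows called, and 80.0% with the block. At the dispersion fitted to the 4 libraries, 0.795, it recovered none of 38 rows changed 4-fold and 27.3% of 55 changed 16-fold, and with the block none and 7.27%. That dispersion was fitted without the pool, and no pool effect was simulated. The recoveries with the block thus do not show the power of that fit in the real libraries. The other calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and DESeq2 1.42.0 served as an alternative.

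A row was called a kit match where its sequence lay within 3 edits of part of a TruSeq oligonucleotide (5' adapter, 3' adapter or stop oligonucleotide) or shared 12 bases in a run with it. The oligonucleotide sequences were written from memory of the kit and were not checked against the maker's documents. This check, and the setting that leaves these rows out and scales the rest to the remaining reads, were chosen after seeing the data, as were the removal of a linear GC trend and the use of a single row per sequence. Alternatives fixed in advance were scaling by median ratios, TMM or column totals, minimum sums of 10, 500 and none, pseudocounts of 0.5 and 10, rows summed per name, pig miRNAs only and the authors' Fisher test.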

Results

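Small RNA was sequenced from exosomes of umbilical cord blood plasma of newborn Yorkshire piglets. Exosomes are small membrane vesicles that carry microRNAs (miRNAs), short RNAs that repress target messenger RNAs, through body fluids. Blood had been drawn at birth from the umbilical vein, which carries oxygenated blood from the placenta to the fetus, and from the umbilical artery, which returns fetal blood to the placenta. Piglets with intrauterine growth restriction (IUGR), in which a fetus fails to reach its growth potential, were set against normal littermates. Each of the 4 libraries (normal vein, IUGR vein, normal artery and IUGR artery) was made from a pool of 3 piglets, so no difference between IUGR and normal had a replicate check. The labels name the vessel of each library, while its condition was read from the letters of the table columns. The tables held 40691 reads for normal vein, 16218 for IUGR vein, 13749 for normal artery and 20144 for IUGR artery, over 664 rows in all, each a miRNA or a variant of its ends. At least part of a read was present in between 289 rows, in IUGR artery, and 475, in normal vein.

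miR-451, the most abundant miRNA of red blood cells, was the leading named miRNA in normal vein, IUGR vein and normal artery, with 24075, 14587 and 14177 normalized reads, and had 3395 in IUGR artery. There, miR-122, the dominant miRNA of hepatocytes, led with 8303 normalized reads. A large part of every library lay in rows that the tables name as predicted candidates, led by PC-3p-343_8063, PC-3p-323_8723 and PC-3p-401_6643. The sequence of PC-3p-323_8723, TCCTCCACGTTCCCGTGG, lies 1 edit from part of the stop oligonucleotide of the TruSeq small RNA kit, taken here as GAATTCCACCACGTTCCCGTGG and not checked against the maker's sequence. Over the tables, 19 rows matched a kit oligonucleotide and held 13.1% of reads in normal vein, 55.6% in IUGR vein, 45.2% in normal artery and 37.6% in IUGR artery. The exact 95% binomial interval for IUGR vein ran from 54.8 to 56.4%. Of the 9020 kit-matching reads in IUGR vein, 4763 lay in PC-3p-343_8063. That row matched only at the limit of 3 edits, with 9 bases shared in a run. Reads in all other rows numbered 35379, 7198, 7530 and 12570.

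Of these other reads, the erythroid list took 62.7% in normal vein, 59.1% in IUGR vein, 55.6% in normal artery and 12.5% in IUGR artery (interval 11.9 to 13.1%). The liver list took 0.181% (0.139 to 0.231%), 2.33% (2.00 to 2.71%), 2.34% (2.01 to 2.70%) and 28.0% (27.2 to 28.8%) in the same order. Platelet and myeloid miRNAs made up 10.3, 6.14, 8.84 and 2.44%, and endothelial and angiogenic miRNAs 3.65, 5.27, 4.97 and 9.44%. The let-7 family, which restrains growth and developmental timing genes, took 0.698, 2.22, 2.10 and 5.72%. All intervals cover counting error only, since reads amplified without molecular identifiers are not independent molecules.

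**Figure D1:**
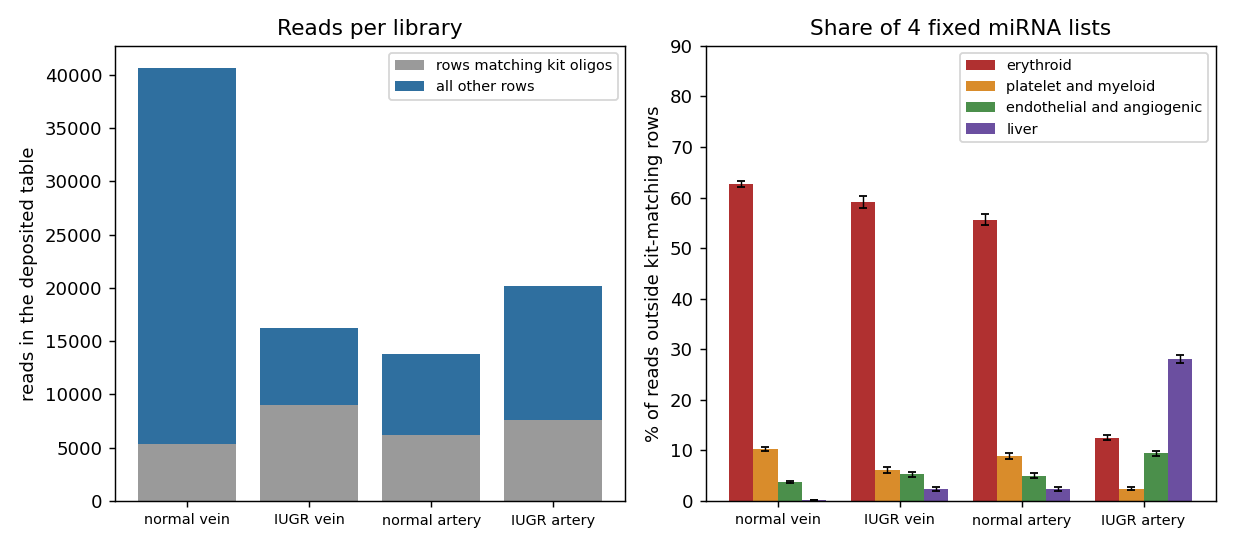
Left, reads per library (y axis) in rows that match kit oligonucleotides (grey) and in all other rows (blue); right, percent of the reads outside kit-matching rows held by 4 fixed miRNA lists, with exact 95% binomial intervals. The liver list reaches 28.0% in IUGR artery against 0.181% in normal vein, while the erythroid list lies at 12.5% in IUGR artery and between 55.6 and 62.7% in the other 3 libraries.

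The first comparison asked how exosomal miRNAs of the umbilical vein differ between IUGR and normal piglets. Liver miRNAs were higher in the IUGR vein library, while many blood-cell miRNAs were lower by an amount that depended on the kit-matching rows. miR-122 had 639 normalized reads in IUGR vein against 85.6 in normal vein, a 7.39-fold difference, with a log2 ratio of 2.89 and a 95% counting interval of 2.40 to 3.42. miR-342, found in immune cells, was 18.8-fold lower in IUGR vein, at 14.1 against 284 normalized reads, and miR-486, an erythroid and muscle miRNA, 3.55-fold lower, at 1448 against 5150, or -1.83 on the log2 scale, which became -0.84 without the kit-matching rows. Among 123 rows with a summed value of at least 50, 14 were at least 2-fold higher and 53 at least 2-fold lower in IUGR vein, and the median log2 ratio was -0.78. The 123 rows included kit matches, and 117 remained without them. Kit matches among the 14 higher rows were PC-3p-343_8063, PC-3p-323_8723, PC-3p-401_6643, PC-5p-1334_984 and PC-5p-9663_41. With the rows matching kit oligonucleotides left out and the rest scaled to the remaining reads, 30 were higher and 25 lower, with a median of 0.09. That setting moved the log2 ratios of the other rows by a median of 0.98 in this comparison, 0.15 between the artery libraries, -0.59 between the vessels of normal piglets and 0.24 between those of IUGR piglets. It also evened out the normalized totals, which were 81049 in normal artery and 64036 in IUGR artery. Shifts that involve these libraries are thus not due to the kit-matching rows alone. Scaling to column totals with all rows kept moved the artery median from -0.30 to 0.03. In vein, median ratio scaling gave 26 higher and 36 lower, with a median of -0.34.

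Both measured members of the liver list were higher in IUGR vein, with a median log2 ratio of 2.60. That lay at percentile 99.8 among 10000 random lists of the same size and abundance. miR-192, a hepatic and intestinal miRNA, had 108 against 20.9 normalized reads, 4.98-fold higher, and miR-215, whose row holds the same sequence, had the same values. Outside the liver, let-7c was 3.59-fold higher in IUGR vein. miR-222, an endothelial regulator of the receptor KIT, was 2.96-fold higher, with 10 reads against 8. miR-450b-5p of the X-linked cluster of miR-424, miR-503 and miR-450 was 2.91-fold higher, with 11 reads against 9. miR-127, an imprinted miRNA of the DLK1-DIO3 locus, was 2.65-fold higher, with 10 reads against 9 and an interval that reached down to a log2 ratio of 0.00. miR-363 was 2.62-fold higher, with 12 reads against 11, and miR-199a-3p 2.54-fold higher. For miR-140-5p, a cartilage miRNA, the log2 ratio was 0.98 with an interval of -0.43 to 2.42.

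The lowest ratios in IUGR vein after miR-342 belonged to miR-193b, with 0.5 against 26.5 reads, and miR-1306-5p, encoded in the transcript of the miRNA processing factor DGCR8, which was 13.3-fold lower. With 1 read each in IUGR vein, miR-1249 was 9.86-fold and miR-328 9.19-fold lower. miR-15b-3p was 8.95-fold, miR-339 8.44-fold and miR-484 7.93-fold lower. In the erythroid list, 11 of 14 members were at least 2-fold lower and 1 higher, with a median of -1.55 at percentile 6.16, inside the 95% range of random lists. Without the kit-matching rows the median was -0.56, and 5 members were lower. In the main setting, miR-92a was 4.09-fold and miR-25 4.07-fold lower, miR-16 2.56-fold and miR-15a 2.23-fold, and without the kit-matching rows the log2 ratios of the last 2 were -0.36 and -0.17. miR-451 had a log2 ratio of -0.72, which became 0.27 in that setting. In the platelet and myeloid list, 5 of 9 members were lower, with a median of -1.28 at percentile 30.7, which became -0.29 with 3 lower in that setting. miR-191 was 5.53-fold lower, miR-223, a regulator of granulocytes, 4.15-fold and miR-23a 3.24-fold, the last at a log2 ratio of -0.71 without the kit-matching rows.

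In the same comparison, miR-150, a lymphocyte miRNA, was 3.97-fold lower in IUGR vein, and 2 of 3 lymphoid and inflammatory members were at least 2-fold lower, with a median of -1.99, or -1.01 without the kit-matching rows. In the 17-92 cluster and its paralogs, which promote proliferation and share miR-92a, miR-25 and miR-363 with the erythroid list, 9 of 14 were lower and 1 higher. The median was -1.24 at percentile 20.2, and without the kit-matching rows -0.25, with 3 lower and 1 higher. Of the endothelial and angiogenic list, 5 of 12 members were lower and 1 higher, with a median of -0.39 that became 0.59 without the kit-matching rows, with 5 higher and none lower. The let-7 family had a median of 0.68 at percentile 97.6, equal to the upper end of the random range, with 1 of 7 members higher and 1 lower. Without the kit-matching rows its median was 1.65, with 6 higher and none lower. It then lay outside the random range, which shifts with the list in that setting. The muscle list had 4 members, none past 2-fold, with a median of -0.86 that became 0.11 without the kit-matching rows, with 1 higher. The miR-30 family stood at -0.58 over 4 members, which became 0.40 in that setting. The X-linked cluster stood at 0.68 over 3 rows, 1 of them past 2-fold, and at 1.64 without the kit-matching rows, with all 3 past 2-fold.

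The authors' deposited table marked 168 rows as different between the vein libraries, 56 higher and 112 lower in IUGR. Recomputed by Fisher's exact test on reads rather than normalized values, 47.0% of these passed the same thresholds. These tests compare the reads of 2 libraries, not the conditions.

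The second comparison set IUGR against normal in the umbilical artery. The liver list was again higher in the IUGR library, joined by the miR-29 family, several endothelial miRNAs and part of the let-7 and miR-30 families, while erythroid miRNAs were lower. miR-122 had 8303 normalized reads in IUGR artery against 784 in normal artery, 10.6-fold higher, with a log2 ratio of 3.40 and an interval of 3.15 to 3.67. miR-451 was 4.17-fold lower in IUGR artery, miR-486 11.3-fold and miR-92a 12.6-fold. Among 135 rows with a summed value of at least 50, 50 were at least 2-fold higher and 57 at least 2-fold lower, with a median log2 ratio of -0.30. The median became 0.35 without the kit-matching rows, 0.36 with median ratio scaling and 0.03 with scaling to column totals alone. The counts without the kit-matching rows were 52 and 53.

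All 5 measured liver members were higher in IUGR artery, with a median log2 ratio of 3.40 at percentile 99.9. They include both strands of miR-122 and both rows of miR-194, which split the same reads, so the 5 are not independent miRNAs. miR-192 had 1545 against 130 normalized reads, 11.8-fold higher, and miR-194, transcribed together with miR-192, 555 against 56.0 under both of its names, 9.75-fold. The 3p strand of miR-122 had 73 reads against 1, 33.8-fold, with a log2 interval of 2.78 to 10.62. Of the miR-30 family, miR-30e-5p was 10.8-fold, miR-30a-3p, with 4 reads in normal artery, 5.99-fold and miR-30c-5p 5.65-fold higher. miR-30a-5p was 6.81-fold lower, and the list median of 1.56 lay at percentile 83.6. The miR-29 family, repressors of collagen genes, was higher in 3 of 3 members, with a median of 3.15 at percentile 97.4. That median equalled the upper end of the random range. miR-29b was 9.11-fold, miR-29c 8.90-fold and miR-29a 2.41-fold higher, with 3, 4.5 and 17.5 reads in normal artery. The log2 intervals of the first 2 ran from 1.63 to 5.57 and from 1.77 to 4.72.

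Of the 12 endothelial and angiogenic members, 5 were higher and 4 lower in IUGR artery, with a median of 0.26. miR-130a, with 5 reads in normal artery, was 8.90-fold, miR-100 6.03-fold, miR-222 5.38-fold and miR-221 4.95-fold higher. Of miR-126, the main miRNA of endothelium, the 3p strand was 3.81-fold higher, while the 5p strand had a log2 ratio of 0.32. miR-125a, with 2 reads in IUGR artery, was 13.0-fold and miR-99a 3.36-fold lower. In the let-7 family, 4 of 8 members were higher and none lower, with a median of 1.09 at percentile 56.5. miR-98, with 4 reads in normal artery, was 7.02-fold, let-7a 5.80-fold and let-7f 2.29-fold higher. miR-145, a smooth muscle miRNA, was 5.73-fold higher in IUGR artery, with 4 reads in normal artery. miR-133a, of striated muscle, was 3.48-fold lower, and the muscle list had a median of 0.47 over 3 members. miR-146a, a brake on NF-kB signalling, was 5.37-fold higher.

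3 miRNAs had no read in normal artery and 18 to 35 in IUGR artery. Against a floor of 3 counts, miR-200a, an epithelial miRNA that represses ZEB1 and ZEB2, was at least 6.29-fold higher. The opossum-named row of miR-210, which is induced by hypoxia, was at least 3.77-fold higher, and miR-216, abundant in exocrine pancreas, at least 3.24-fold. The pig-named miR-210 row had 34 against 9 reads, 2.02-fold, with a log2 interval of -0.06 to 2.27. miR-200b, with 17 reads against 1, was 7.98-fold higher. The epithelial list of 2 members had a median of 4.90, or 2.83 with the undetected member at its bound and 2.81 with a pseudocount of 10, and the hypoxia list of 2 rows 3.55, or 1.46 at the bound and 1.92 with that pseudocount.

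In the erythroid list, 10 of 13 members were at least 2-fold lower in IUGR artery and 2 higher, with a median of -2.74 at percentile 0.39. miR-15b was 15.7-fold, miR-25 10.6-fold, miR-15a 6.66-fold and miR-144, processed from the same transcript as miR-451, 5.16-fold lower. The members that were higher were miR-363, 4.00-fold, with 38 reads against 5, and a row named miR-16c, 15.4-fold, with 33 reads against 1 and a log2 interval that starts at 1.57. Platelet and myeloid miRNAs were lower in 7 of 9 members and higher in 1, with a median of -1.99 at percentile 9.12. miR-339 was 33.0-fold, miR-191 11.6-fold, miR-223 9.34-fold and miR-21 3.98-fold lower, while miR-142-3p was 3.03-fold higher. The 17-92 list was lower in 9 of 14 members and higher in 2, with a median of -2.33 at percentile 2.10, which became -2.06, inside the random range, with 1 row per sequence. miR-106b, with 2 reads in IUGR artery, was 22.2-fold and miR-17 5.04-fold lower, and miR-20b, with 4 reads in normal artery, 3.66-fold higher.

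The lowest ratio in artery belonged to the pig miRNA miR-9841-3p, with 84 reads in normal artery and none in IUGR artery, at least 51.9-fold lower. miR-15b-3p was at least 16.7-fold lower, miR-342 at least 14.2-fold, and miR-1306-5p and miR-6529a at least 7.42-fold. miR-423-3p was 24.7-fold and miR-320, with 1 read in IUGR artery, 22.8-fold lower. The lymphoid and inflammatory list had a median of -0.53 over 4 members, which became 0.14 with median ratio scaling, and the single neural member, miR-128, a log2 ratio of -0.30. The authors' deposited table marked 331 rows as different between the artery libraries, 103 higher and 228 lower in IUGR, of which 211 had no read in 1 of the libraries and 37.8% passed on reads.

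The changes in vein and artery shared no library and were compared across 102 rows measured in both. The labels' protocol was read as pooling the same 3 piglets of a condition for both vessels, so a difference between pools can recur in both changes. Across rows, Pearson's r was 0.71 and Spearman's rho 0.71, each with a permutation p of 1e-05, the smallest that 100000 resamples can give, and 1e-05 after Benjamini-Hochberg adjustment over 2 relations. Rows are not independent replicates, and the p covers the pairing of rows and not the spread between pools. The sign was the same in 79.4% of rows. miR-342, miR-15b-3p, miR-339, miR-191, miR-486, miR-92a, miR-25 and miR-223 were among 35 rows at least 2-fold lower in both vessels, where 22.3 would be shared by independent lists. The 5 rows at least 2-fold higher in both were miR-122, miR-192, miR-215, miR-222 and miR-363, where independent lists would share 2.59. These counts depended on scaling, with 18 lower and 16 higher in both among the 96 rows left without the kit-matching rows. Median ratio scaling gave 22 and 12. Among the 5 higher rows, miR-192 and miR-215 hold the same reads. In vein, miR-222 had 10 reads in IUGR against 8 in normal and miR-363 12 against 11, with log2 intervals that start at 0.13 and 0.12. miR-221 alone was past 2-fold in opposite directions, at -1.32 in vein and 2.31 in artery, and its vein value became -0.34 without the kit-matching rows. Without the 2 rows farthest from the median vein ratio, r was 0.69.

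**Figure D2:**
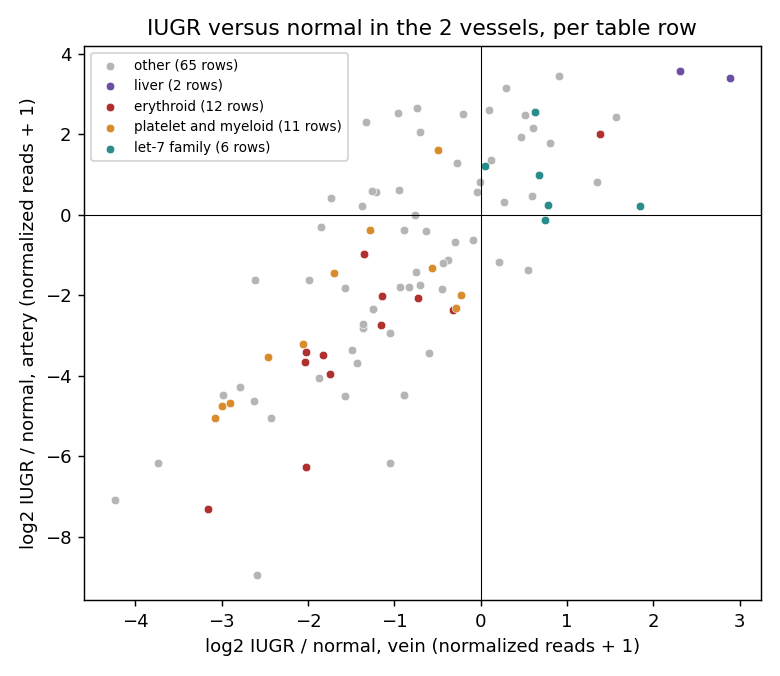
Log2 ratio of IUGR over normal normalized reads (plus 1) in vein (x axis) and artery (y axis), a point for each row measured in both vessels outside the kit-matching rows, coloured by list. The liver rows stand at the upper right, with miR-122 at 2.89 and 3.40, and most erythroid rows at the lower left, with miR-486 at -1.83 and -3.49.

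The third comparison asked how the vessels differ in normal piglets. Liver miRNAs were lower in the vein library than in the artery library. miR-122 had 85.6 normalized reads in vein against 784 in artery, 9.06-fold lower, with a log2 ratio of -3.18 and an interval of -3.72 to -2.70. miR-451 was 1.70-fold higher in vein, a log2 ratio of 0.76 that became 0.16 without the kit-matching rows. miR-486 was 2.55-fold and miR-191 4.47-fold higher. Of the rows that passed the same minimum, 33 were at least 2-fold higher and 35 at least 2-fold lower in vein, with a median log2 ratio of 0.02. Without the kit-matching rows 14 were higher and 43 lower, with a median of -0.41, and with TMM scaling 40 were higher and 25 lower, with a median of 0.22.

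All 4 measured liver members were lower in normal vein, with a median of -3.09 at percentile 0.085, or -2.12 with a pseudocount of 10. As both rows of miR-194 split the same reads, 1 row per sequence leaves 3 members, all lower, with the same median at percentile 0.305. miR-194 was 8.50-fold lower, with 3 against 9.5 reads, and miR-192 and miR-215 5.96-fold. In the let-7 family, 4 of 9 members were lower and none higher, with a median of -0.96 at percentile 2.64, or -1.55 with 8 lower without the kit-matching rows. An end variant of let-7a was 18.6-fold lower, with 1 read against 9, and the main let-7a row was 3.21-fold, let-7c 2.28-fold and let-7i 2.27-fold lower. miR-222 was 4.42-fold, miR-30e-5p 3.97-fold, miR-202-5p 3.96-fold, pig-named miR-210 3.33-fold and miR-125b 2.25-fold lower. miR-144, of the same transcript as miR-451, was 2.22-fold lower in vein. The row named miR-3168, 19.1-fold lower, matched the kit's 5' adapter and is not described as a miRNA.

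Higher in normal vein were an end variant of miR-486, 14.9-fold, and miR-93-3p, 14.2-fold, each with 1 read in artery. miR-193b, with 0.5 reads in artery, was 13.0-fold, miR-365-3p, with 2, 6.48-fold, miR-10b, encoded in a HOX cluster, 5.59-fold, miR-145 4.53-fold, miR-423-3p 4.46-fold and miR-150 3.70-fold higher. Erythroid members were higher in 3 of 15 and lower in 1, with a median of 0.83 at percentile 90.1, and 17-92 members higher in 5 of 14, with a median of 0.84 at percentile 91.7. Without the kit-matching rows these medians were 0.23 and 0.24, with 1 and 2 members higher, and miR-486 stood at a log2 ratio of 0.75. miR-19a was 3.69-fold and miR-19b 2.85-fold higher, the latter at 0.91 in that setting. The platelet and myeloid median of 0.28, the lymphoid one of 0.23 and the endothelial one of 0.48 each changed sign without the kit-matching rows, to -0.32, -0.36 and -0.11. The authors' deposited table marked 230 rows, 83 higher and 147 lower in vein, and 32.6% of them passed on reads.

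The fourth comparison set the vessels against each other in IUGR piglets. Liver, miR-30 and miR-29 miRNAs were lower in vein and 17-92 miRNAs higher. miR-122 had 639 normalized reads in vein against 8303 in artery, 13.0-fold lower, with a log2 ratio of -3.70 and an interval of -3.96 to -3.45. miR-451 was 4.30-fold higher in vein, miR-486 8.09-fold and miR-92a 6.15-fold. Among 120 rows, 38 were at least 2-fold higher and 53 at least 2-fold lower, with a median log2 ratio of -0.61. The median was -0.40 without the kit-matching rows, -0.78 with median ratio scaling and -0.86 with scaling to column totals alone. The IUGR artery library also enters the second comparison, so the values of these comparisons are not independent.

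All 5 liver members were lower in IUGR vein, with a median of -3.95 at percentile 0.515. They include both strands of miR-122 and both rows of miR-194, which split the same reads, so the 5 are not independent miRNAs. miR-194 was 53.4-fold lower, with 2 reads against 174.5, and miR-192 14.2-fold. All 5 measured miR-30 members were lower, with a median of -3.61, or -3.37 with the undetected member at its bound, at percentile 4.05. miR-30e-5p was 22.9-fold and miR-30c-5p 12.2-fold lower, and miR-30a-3p, with no read in vein, at least 10.4-fold. The 3 miR-29 members were lower, with a median of -4.40 at percentile 2.42, equal to the lower end of the random range. With a pseudocount of 10 the median was -3.39, and the median member, miR-29b, had 1.5 reads in vein. let-7a was 12.1-fold, miR-98 8.72-fold and let-7f 4.31-fold lower, and the let-7 median was -1.42 at percentile 29.2. miR-146a was 16.1-fold, miR-221 8.21-fold, miR-222 8.03-fold, miR-100 6.81-fold and miR-126-3p 3.09-fold lower. The 5p strand of miR-126 went the other way, at a log2 ratio of 0.65 with an interval of 0.14 to 1.16. With no read in vein, miR-338 was at least 6.54-fold, miR-20b at least 6.31-fold and the opossum-named miR-210 row at least 4.73-fold lower.

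The 17-92 list was higher in IUGR vein in 8 of 13 members and lower in 2, with a median of 1.86 at percentile 98.99. miR-106b, with 2 reads in artery, was 9.72-fold, miR-93 8.40-fold, miR-25 5.71-fold and miR-17 3.63-fold higher. Erythroid members were higher in 6 of 11 and lower in 2, with a median of 1.32 at percentile 96.6, and platelet and myeloid members higher in 5 of 9 and lower in 1, with a median of 1.31 at percentile 94.4. miR-423-3p was 17.9-fold, miR-320, with 1 read in artery, 17.1-fold, miR-125a, with 2, 16.1-fold, miR-423-5p 11.5-fold, miR-191 9.35-fold and miR-339 8.20-fold higher. The X-linked cluster was higher in 3 of 3 rows, with a median of 4.28 at percentile 95.5, or 2.36 with a pseudocount of 10, and 2 of these rows split the same reads of miR-424. miR-450b-5p had 11 reads in vein and none in artery, at least 5.42-fold higher, and miR-424 10.5 against 0.5 reads. miR-9841-3p, with 13 reads against none, was at least 6.41-fold higher. The authors' deposited table marked 84 rows as higher and 108 as lower in vein, and 59.4% of them passed on reads.

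**Figure D3:**
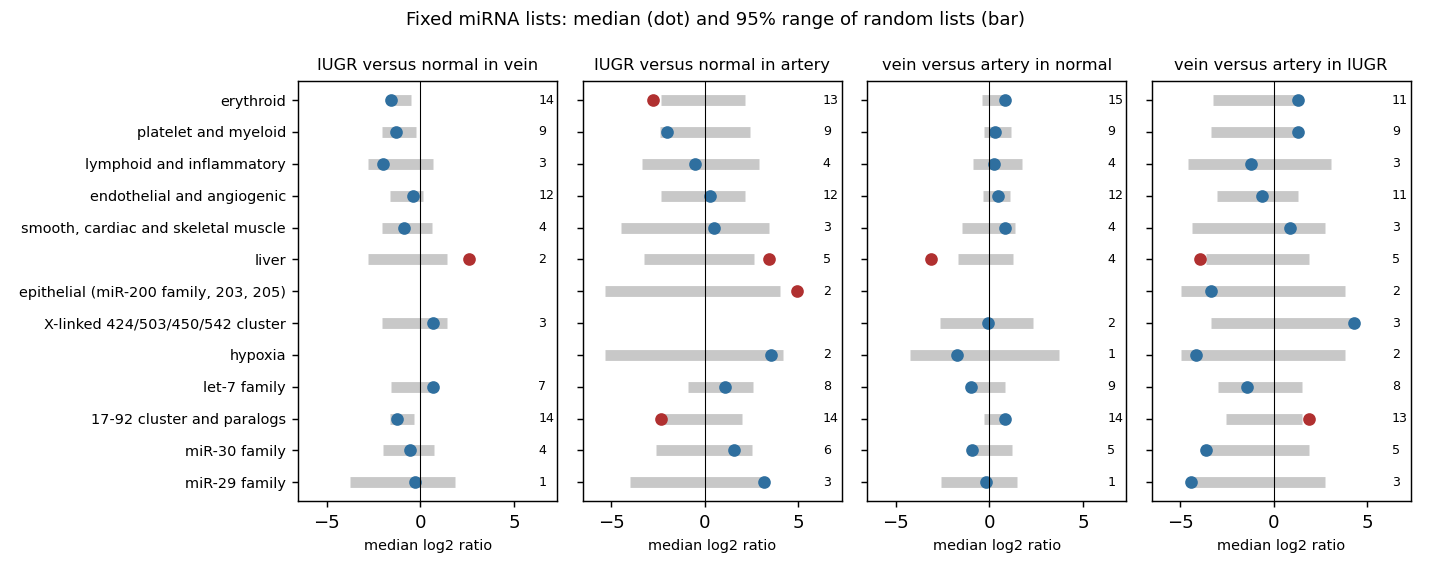
Median log2 ratio of each fixed list (dots, x axis) in the 4 comparisons, with the central 95% range of 10000 random lists of the same size and abundance (grey bars) and the number of measured members at the right; red dots lie outside that range. The liver list lies outside it in all 4 comparisons, at 2.60, 3.40, -3.09 and -3.95.

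The vessel difference in normal and in IUGR piglets shared no library, and across 94 rows measured in both r was 0.63 and rho 0.60, each with a permutation p of 1e-05, the smallest possible, and 67.0% of rows had the same sign. miR-122, miR-192, miR-194, miR-30e-5p, miR-222 and let-7a were among 14 rows at least 2-fold lower in vein in both, where independent lists would share 8.24. miR-191, miR-423-3p, miR-10b, miR-125a and miR-150 were among 15 higher in both, where independent lists would share 8.19. Without the kit-matching rows, 17 were lower and 6 higher in both.

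Vein against artery was tested over all 4 libraries, 2 on each side. IUGR against normal was not tested over both vessels, since the labels' protocol was read as pooling the same 3 piglets of a condition for vein and artery, which the labels do not state outright. For vein against artery, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 135 rows, with 19 at an unadjusted p under 0.05 and a smallest adjusted p of 0.167. In data simulated at the dispersion of these libraries the test found none of the rows changed 4-fold, so the absence of calls does not show that the vessels are alike. miR-194 had a log2 ratio of -5.48 with a standard error of 1.82 and an adjusted p of 0.167 in edgeR, lower in vein in both pools. The end variant of let-7a stood at -4.70 with a standard error of 1.81 and an adjusted p of 0.259, and miR-30e-5p at -4.12 with a standard error of 1.70 and an adjusted p of 0.316. DESeq2 called 4 rows, all lower in vein: both rows of miR-194 (adjusted p of 0.0168), miR-30e-5p (0.0460) and a predicted candidate, PC-5p-10732_35 (0.0460). Left out in turn, the normal artery library gave 18 rows higher and 29 lower in vein in edgeR, the IUGR vein library 1 and 4, the normal vein library 2 and 0 and the IUGR artery library none, where the lone library of a vessel was assumed to vary as the other vessel's did.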

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

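The test of depth and that of GC content below were set before their results were seen, and those of kit reads, candidate reads and red-cell miRNAs after. miR-145, a smooth muscle miRNA, was higher in vein than in artery in the normal pool, at a log2 ratio of 2.18 (interval 0.79 to 4.15, with 58 and 4 reads), and lower in vein in the IUGR pool, at -1.29 (interval -2.37 to -0.36, with 12 and 44 reads). The difference of -3.47 between the pools drew attention because the pools moved opposite ways, each at least 2-fold under both scalings and with counting intervals that exclude equality. It was not tested, with 1 library per pool and vessel. miR-145 was the only miRNA within these limits among 86 compared, and none of 91 was for IUGR against normal. Others, such as miR-144 (-1.15 in normal and 0.90 in IUGR), changed sign without passing 2-fold in each under the main scaling. Without the kit-matching rows miR-144 did pass it in each, at -1.75 in normal and 1.14 in IUGR. Its counting intervals also excluded equality, at -1.38 to -0.92 and 0.50 to 1.30. In that setting 5 rows were past 2-fold in opposite directions, against 2 in the main setting.

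Predicted candidates held between 13.2 and 55.8% of the reads of a library. Of all candidate reads, 98.4% lay in 18 rows that match kit oligonucleotides, 11 of all 19 matching rows being closest to the stop oligonucleotide, 7 to the 5' adapter and 1 to the 3' adapter. The largest of these rows, PC-3p-343_8063, matched only at the limit of 3 edits. None of 1660 shuffled sequences and none of 245 pig miRNA rows matched by the same rule. These reads are thus consistent with oligonucleotides of the library preparation, and no biological explanation was tested. They numbered between 5312 and 9020 per library, while the other reads ranged from 7198 to 35379.

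In vein, 53 rows were lower and 14 higher in IUGR, the higher ones including kit-matching rows. With the normal vein library thinned to the depth of the IUGR vein library and scaled back, a median of 53.5 rows over 20 draws were lower (50 to 59). Such thinning leaves the expected ratio of each row unchanged, so it cannot decide whether a difference in depth played a part. Kit reads taking up library depth remain a candidate explanation: under scaling to totals their shares alone would shift all other rows by -0.97, against a median log2 ratio of -0.89 seen, which became 0.0949 once they were left out. That a median near 0 is not fixed by this rescaling is shown by the other comparisons, where it left medians of 0.35, -0.41 and -0.40. Growth restriction itself stays open and untested, with 1 pool on each side.

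Liver miRNAs were higher in the IUGR library of both vessels. Kit reads were argued against for the liver members that passed the minimum sum. Under scaling to totals the kit shares would lower all other rows in IUGR vein by 0.97 and raise them in IUGR artery by at most 0.19 on the log2 scale. The lowest such liver member stood at 2.31 in vein and 3.29 in artery. In vein only miR-122 and miR-192 passed, and miR-194 did not, with 3 reads in normal vein and 2 in IUGR vein. A linear GC trend was argued against, with liver medians of 3.23 or more in both vessels after its removal and lowest members of 2.84 and 3.39. Fewer red-cell miRNAs in IUGR artery would raise all other rows alike, by 0.98 given the erythroid shares, while the lowest liver member without the kit-matching rows stood at 3.44. With the erythroid list left out as well, the liver median in artery was 2.58. Differences between pools other than growth, such as handling of the blood, and growth restriction itself stay open and untested, so that more hepatic RNA in IUGR cord plasma may be followed up only as a hypothesis.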

How the results depend on the processing

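Settings that leave out kit-matching rows, remove a GC trend or use a single row per sequence were chosen after seeing the data. Of the pairs of a main result and an alternative, 84 kept the size or correlation and 56 moved, a share counting as moved when its count changed over 1.5 times or it left the 95% binomial interval of the main share. The planned rule used the count alone, and the interval was added after seeing the data. Of 54 pairs of list and comparison, 10 medians changed sign in at least 1 setting, none of them outside the range of random lists in the main setting, 6 pairs moved outside that range in at least 1 setting, and 1 moved inside, the 17-92 list in artery with 1 row per sequence (-2.06). Rows at least 2-fold higher and lower, with their percent of the rows tested, made up 11.4% and 43.1% in IUGR versus normal vein, 37.0% and 42.2% in artery, 24.6% and 26.1% between normal vessels and 31.7% and 44.2% between IUGR vessels.

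In vein, they were 30 (13.0%) and 93 (40.4%) at a minimum sum of 10, 5 (15.6%) and 16 (50%) at 500, 74 (14.3%) and 263 (50.9%) with no filter and 9 (10.23%) and 34 (38.6%) with pig miRNAs only. Median ratio scaling gave 26 (21.1%) and 36 (29.3%), and leaving out kit-matching rows 30 (25.6%) and 25 (21.4%). The Fisher counts here and below take rows by p and direction alone, with no 2-fold limit and no minimum sum. The authors' Fisher test so counted gave 70 (13.5%) and 132 (25.5%) at 0.05 and 35 (6.77%) and 104 (20.1%) at 0.01. With the 2-fold limit it gave 56 and 112 at 0.05. In artery, they were 72 (28.0%) and 53.7% at 10, 15 (38.5%) and 15 (38.5%) at 500, 30.1% and 276 (57.3%) with no filter and 33 (36.3%) and 37 (40.7%) with pig miRNAs only, and by Fisher 116 (24.1%) and 235 (48.8%) at 0.05 and 112 (23.2%) and 28.4% at 0.01. Between normal vessels, they were 58 (22.3%) and 88 (33.8%) at 10, 12 (32.4%) and 10 (27.03%) at 500, and 202 (34.8%) and 212 (36.5%) with no filter. There, pig miRNAs only gave 21 (22.8%) lower, TMM 25 (18.7%) lower, leaving out kit-matching rows 14 (11.1%) higher, and Fisher 111 (19.1%) and 160 (27.5%) at 0.05 and 83 (14.3%) and 73 (12.6%) at 0.01. Between IUGR vessels, they were 79 (37.8%) higher at 10, 8 (24.2%) and 15 (45.5%) at 500, and 44.7% and 158 (38.6%) with no filter, and by Fisher 94 (22.98%) and 118 (28.9%) at 0.05 and 84 (20.5%) and 111 (27.1%) at 0.01. Minimum sums, pig miRNAs only, no filter and the Fisher counts change how many rows are tested, and the cause of the other shifts was not tested.

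For vein against artery over both pools, DESeq2 called 4 rows lower in vein against 0 in edgeR. Leaving out a library gave between 0 and 18 higher and between 0 and 29 lower. With the pool as a replicate block, 0 rows were higher and 0 lower, with 16 at an unadjusted p under 0.05 and a smallest adjusted p of 0.207, so the paired fit changed no call. A pseudocount of 10 was not run there because the test uses counts. The correlation of the IUGR change between vessels ran from 0.55 to 0.77 over its alternatives, and that of the vessel difference from 0.52 to 0.67. Depth limits a fold against normal artery, the shallowest library, to values above 17.7 normalized reads.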

Other observations

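miR-122 and miR-192 were each lowest in normal vein and highest in IUGR artery, and lay between these in the other 2 libraries. miR-122 had 85.6, 639, 784 and 8303 normalized reads in normal vein, IUGR vein, normal artery and IUGR artery. miR-194 had 5.71, 9.40, 56.0 and 555 and was also highest in IUGR artery. With 3 reads in normal vein and 2 in IUGR vein, its vein libraries cannot be ranked. miR-30e-5p, with 30, 23, 39 and 786.5 reads, and miR-100, with 309 reads in IUGR artery and 27.5 in normal artery, stood apart mainly in IUGR artery. Of the reads outside kit-matching rows, the hypoxia miRNA miR-210 took 0.557% in IUGR artery (interval 0.434 to 0.703%) and between 0.0254 and 0.133% in the other libraries. The X-linked cluster went the other way, at 0.0159% in IUGR artery (0.00193 to 0.0575%) and 0.514% in IUGR vein (0.362 to 0.708%).

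Imprinted DLK1-DIO3 miRNAs, which are abundant in placenta and fetal tissues, took 0.361% of reads outside kit-matching rows in IUGR vein (interval 0.236 to 0.529%), 0.223% in normal vein (0.177 to 0.278%), 0.173% in normal artery (0.0920 to 0.295%) and 0.0716% in IUGR artery (0.0327 to 0.136%). Epithelial miRNAs took 0.469% in IUGR artery (0.357 to 0.605%) against 0.0531% in normal artery (0.0145 to 0.136%). Neural miRNAs lay between 0.0972 and 0.191% in the 4 libraries, with overlapping intervals.

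Rows rich in G and C tended to have lower IUGR to normal ratios: outside the kit-matching rows, Spearman's rho of the log2 ratio with GC content was -0.48 across 117 rows in vein and -0.29 across the rows in artery, against 0.23 and 0.11 for the vessel differences. For vein, 19 of 517 recomputed Fisher p-values lay near no value of the authors' deposited p-value column. In that column 17 steps in a row are equal, at 0.000184, while the longest such run in the other tables is 1. Of the rows marked in the authors' deposited tables, 44.0% in vein, 65.9% in artery, 63.0% between normal vessels and 45.3% between IUGR vessels had fewer than 10 reads over both libraries.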
